A study of Mus musculus with 39 samples.

How the data were processed

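RNA was sequenced from microglia sorted from the striatum of male mice aged 8 to 10 weeks. Per the labels, live cells were gated as CD11b positive, CD45 low and P2RY12 positive, 18 hours after an intraperitoneal injection of lipopolysaccharide (LPS) or saline. Complementary DNA was made with a linear amplification kit that keeps no strand information and removes no ribosomal RNA, per the labels. Each library carries a prenatal term (CON or MIA, maternal immune activation in the series design), an arm term (CON or PLX, which the labels do not define) and an injection (LPS or SAL). An arm is written here as prenatal term, colon, arm term, so that MIA:CON is prenatal MIA without PLX.

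The deposited table holds estimated counts per gene, for 55487 gene identifiers and 39 libraries, and 14.71% of its nonzero values are not whole numbers. STAR, RSEM and DESeq2 are named without versions or roles, per the submitters' processing notes. The genome build and annotation are not given in the sources used here. Gene symbols were taken from GENCODE release M21, in which 54349 identifiers matched with their version and 55141 matched in all. Genes without a symbol held 0.013% of the counts. Values were rounded to whole numbers before fitting.

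The titles of 2 libraries, CON_CON_LPS replicate 3 and MIA_PLX_SAL replicate 1, say that they are to be excluded, without a reason. The remaining 37 libraries form 8 groups of 3 to 6. Their totals ran from 1510020 to 5746239 counts with a median of 3095162. The labels do not say that replicates are separate animals, so p-values measure only the spread between these samples, which may be technical. They do not say what a replicate number shares between groups either, so no block was used.

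Genes were kept by filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total 15), which left 13417 genes and removed 15585. One model with a mean per group was fitted to the 37 libraries by edgeR quasi-likelihood with TMM normalization and robust dispersion (R 4.3.3). The common dispersion was 0.0972. Each contrast was adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05 with no fold limit. Tests were two-sided. Standard errors (SE) of log2 fold changes were taken as the change divided by the square root of the F statistic. The contrasts were LPS against saline in each of the 4 arms, MIA against CON and PLX against none within each injection, and the interactions. The 4 LPS contrasts share no libraries.

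The size of the LPS response was the signed mean log2 fold change over genes that responded in the other 2 arms (adjusted p under 0.05 by edgeR, absolute log2 fold change over 1). Its difference between MIA and CON was tested by exact permutation of the prenatal label within injection, two-sided. For 26 gene lists, members past the threshold were counted over all genes and adjusted over the list alone. Each list was tested against other genes by camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and again with an estimated one, adjusted by Benjamini-Hochberg over the lists of a contrast. A list score is the mean log2 CPM (counts scaled to a common library total) of the list in a library (prior count 2), compared between groups by exact permutation, two-sided.

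The lists, contrasts, tests and the rule for named genes were fixed before the data were examined. The lists were homeostatic microglia, NF-kB targets and inflammatory mediators, chemokines, interferon-stimulated genes, MHC class I and antigen processing, MHC class II, LPS sensing and its negative regulators, complement and phagocytic receptors, disease-associated microglia, brain-engrafted macrophage genes, cholesterol synthesis, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, cell cycle, immediate early and dissociation stress, and unfolded protein response. Further lists held markers of other cell types, namely neurons, astrocytes, oligodendrocyte lineage, endothelial and mural cells, border-associated macrophages, monocytes, neutrophils, lymphocytes and erythroid cells. For LPS in CON:CON the rule named the 8 higher and 8 lower called genes with the largest change, an average log2 CPM of at least 4 and no overlap between LPS and saline libraries. For other contrasts it named the 5 higher and 5 lower called genes with the smallest p at that level. From each list it took up to 4 members with the smallest p and the member with the largest. P2ry12, Itgam, Ptprc, Tmem119, Cx3cr1, Csf1r, Tnf, Il1b, Ccl2, Cxcl10 and Tlr4 were named always, and predicted genes without a name were skipped. The values of 1 gene that the rule named are not reported here.

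Where all libraries of a group were at 0, a fold is given as a lower bound against 3 counts over the group. With 1 to 3 counts it is a ratio of counts with its 95% interval. Intervals and floors cover counting error only. Alternatives tried were RLE size factors, DESeq2 1.42.0, limma voom with quality weights, no filter, a stricter filter (CPM of at least 5 in 4 libraries), a replicate block, fitting only the compared groups, including both marked libraries, and leaving out each library in turn, and for the response size also no fold limit, a smaller prior count and the preset lists. A pair of alternatives was added after seeing the data: a covariate from the residuals, and leaving out MIA_CON_LPS replicate 6 and CON_PLX_SAL replicate 2 together. Comparisons of every pair of libraries by chi-square over genes at an average log2 CPM of at least 4, and scores, member counts and camera for 5 lists without each library were also added after seeing the data.

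The steps were tested on simulated data. With changes put into 200 genes, edgeR recovered 37.3%, 92.5% and 97% of log2 changes of 1, 2 and 3 for LPS in CON:CON, and called 3 unchanged genes. For the interaction of MIA and LPS without PLX it recovered 14.9%, 80.6% and 89.4% and called 4 unchanged genes. A simulated response ratio of 0.6 was estimated as 0.609.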

Results

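The libraries measured gene expression in sorted striatal microglia at 18 hours after LPS, a bacterial cell wall component that activates innate immune cells, or after saline. There were 4 libraries each of CON_CON_LPS, CON_CON_SAL, CON_PLX_SAL and MIA_CON_SAL, 6 each of CON_PLX_LPS, MIA_CON_LPS and MIA_PLX_LPS, and 3 of MIA_PLX_SAL. Mean totals per library ran from 2578872 ± 625366 counts (SD, n = 6) in MIA_PLX_LPS to 4253882 ± 1214367 (SD, n = 6) in CON_PLX_LPS. Mitochondrial ribosomal RNA took 12.6% of counts in CON_CON_LPS (6.14% to 16.6% per library), 16.9% in MIA_CON_LPS, 16.8% in CON_PLX_LPS and 16.1% in MIA_PLX_LPS, and 10.7% to 12.6% in the saline groups. MIA_CON_LPS replicate 6, which is used here, differed from MIA_PLX_SAL replicate 1, whose title says exclude, by little more than counting error (chi-square per degree of freedom 1.66 over 6719 genes, the lowest of 741 pairs, with 2.85 for the next pair and at least 13.1 between replicate 6 and any other library). Values without replicate 6 are given below for the results that were run again without it and moved. The first principal component held 41.24% of the variance. Of the 55487 listed genes, 29115 had a count in some library.

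The first question was what LPS does to microglia of mice with neither MIA nor PLX. Saa3 (ENSMUSG00000040026.8), an acute-phase serum amyloid, stood at 296 ± 211 CPM (SD, n = 4) after LPS and at 0 in all saline libraries, at least 1370-fold higher. Marco, a scavenger receptor, was at least 392-fold higher, Acod1, which makes itaconate, at least 239-fold, and Trem1, a receptor that amplifies myeloid activation, at least 146-fold. Il1r2, a decoy receptor for interleukin 1, had a count ratio of 620 (95% interval 212 to 3010), and Zbtb16, a zinc finger transcription factor, one of 676 (187 to 5590). Cd300lf, a myeloid surface receptor, rose by 8.68 ± 0.657 on the log2 scale (SE), and Lcn2, a lipocalin that binds bacterial siderophores, by 7.87 ± 1.38.

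The genes that fell furthest in CON:CON included several that mark resting microglia. Gpr34, a lysophospholipid receptor, changed by -3.70 ± 0.887 (log2, SE) and the fructose transporter Slc2a5 by -3.72 ± 0.790. Upk1b, a tetraspanin-family membrane protein, changed by -4.52 ± 0.573, the matrix protein Npnt by -4.39 ± 0.636, Tspan18 by -3.94 ± 0.873, Gpr165 by -3.24 ± 0.642 and Cfap74 by -3.14 ± 0.684. Iqcn went from 170 ± 82.3 to 0.462 ± 0.318 CPM (SD, n = 4 each). P2ry12 (ENSMUSG00000036353.13), the purinergic receptor used in the gate, went from 2351 ± 265 to 279 ± 87.6 CPM (SD, n = 4 each), a log2 change of -3.08 ± 0.381 with an adjusted p of 3.64e-07 by edgeR. The other gate genes, Itgam (-0.12) and Ptprc (0.18), did not pass the test, nor did the LPS receptor gene Tlr4 (-0.09), Cx3cr1 (-1.34) or Csf1r (-0.43). Tmem119, another microglial marker, fell by 1.64. With both marked libraries included, Gpr34 (-1.69), Slc2a5 (-1.88), Gpr165 (-1.62) and Tmem119 (-1.07) were not called.

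Cytokine genes rose beside these. Tnf, an inflammatory cytokine, went from 66.1 ± 23.8 to 861 ± 696 CPM (SD, n = 4 each), a log2 change of 3.70, and Il1b, the precursor of interleukin 1 beta, rose by 5.14. The chemokine genes Ccl2 and Cxcl10 rose by 2.60 and 3.45, and Ccl2 was not called without CON_CON_LPS replicate 2 (1.87) or 5 (2.38) or CON_CON_SAL replicate 2 (2.59), 3 (2.42) or 4 (2.53). By edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 1840 genes were higher and 1320 lower after LPS in CON:CON. Of these, 1168 and 928 changed more than 2-fold.

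**Figure D1:**
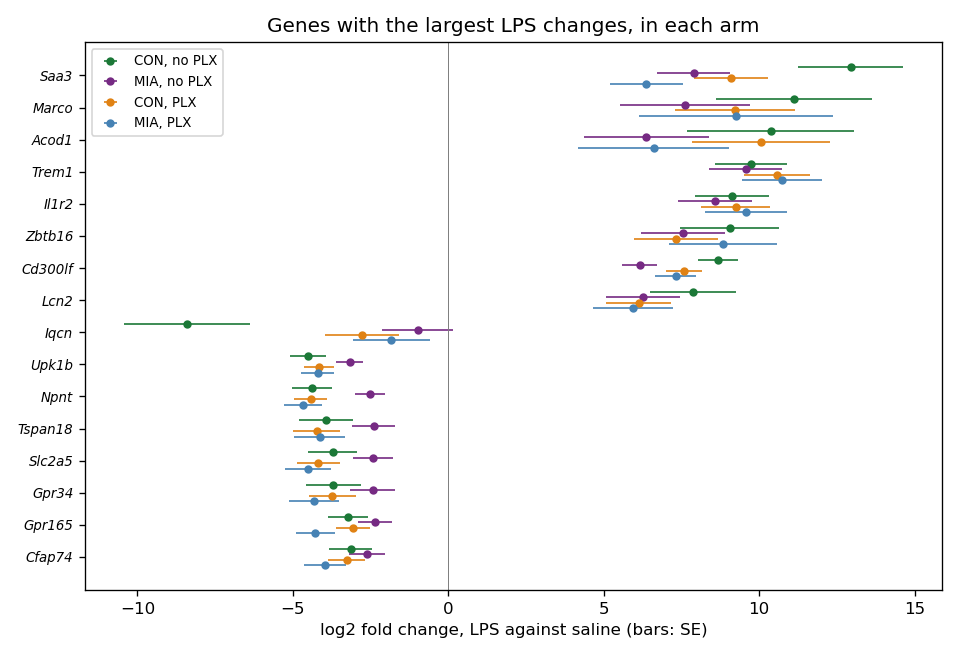
Log2 fold change of LPS against saline (horizontal axis) for the 16 genes named by the rule in CON:CON (vertical axis), in each of the 4 arms, with bars of 1 SE. Genes such as Cd300lf lie to the right of 0 and genes such as Upk1b to the left in every arm, while the bars of Iqcn reach widely; fitted values of genes at 0 in saline are no bounds.

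Gene groups in CON:CON moved as follows. Of 17 homeostatic microglia genes 14 fell and 0 rose (15 adjusted over the list alone), among them Siglech, a sialic acid receptor (-1.96 ± 0.269), the TGF-beta receptor gene Tgfbr1 (-1.25 ± 0.225) and the transcription factor gene Mef2c (-1.12 ± 0.224), while Sparc (-0.34 ± 0.173) did not pass. The camera adjusted p was 4.34e-13, and the adjusted p = 0.129 with an estimated correlation. Of 29 interferon-stimulated genes, which restrain viruses and carry interferon signals, 27 rose (27 adjusted over the list alone), with Ifi204 at 5.32 ± 0.381, Stat2 at 2.63 ± 0.313, Rtp4 at 3.71 ± 0.470 and Zbp1 at 4.29 ± 0.582, and Ifit3b at 0.69 ± 0.819 not called. Its camera adjusted p was 4.34e-13, and the adjusted p = 0.161 with an estimated correlation. Of 23 NF-kB targets and inflammatory mediators 19 rose and 1 fell (20 and 1 adjusted over the list alone). The transcriptional regulators Bcl3 (3.87 ± 0.447) and Cebpb (2.45 ± 0.437) rose, Nfkb1 (0.17 ± 0.252) was not called, and Marcks, an actin-binding kinase substrate, fell by 1.25. Camera gave this list an adjusted p of 3.72e-05, and an adjusted p = 0.482 with an estimated correlation.

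Among 14 chemokines, which attract leukocytes, 11 rose and 1 fell in CON:CON (12 rose adjusted over the list alone). Ccl5 rose by 6.83 ± 1.16, Cxcl2 by 5.83 ± 1.10 and Cxcl16 by 1.93 ± 0.378. Cxcl9 was at least 41-fold higher, Ccl9 was not called, and Ccl6 fell by 1.55. The camera adjusted p was 0.00675, and the adjusted p = 0.482 with an estimated correlation. For MHC class I and antigen processing, which displays peptides to cytotoxic T cells, 8 of 14 rose (9 adjusted over the list alone), with the transactivator Nlrc5 at 3.54 ± 0.470, Tap1 at 1.48 ± 0.275 and H2-D1 at 1.15 ± 0.244, and Tap2 at -0.04 ± 0.269 not called. Camera gave an adjusted p of 0.000441, and an adjusted p = 0.325 with an estimated correlation. Of 18 complement and phagocytic receptor genes 10 rose (10 adjusted over the list alone, where 1 also fell), with C5ar1 at 2.96 ± 0.368, C3 at 4.27 ± 0.541, C4b at 4.73 ± 0.692 and Fcgr3 at 1.01 ± 0.165, and C1qc at -0.01 ± 0.265 not called. Its camera adjusted p was 0.00507, and the adjusted p = 0.482 with an estimated correlation. Of 35 cytosolic ribosomal protein genes 14 rose (18 adjusted over the list alone), with Rps19 at 1.40 ± 0.333 and Rps2 at 1.27 ± 0.315, and Rpl30 at 0.26 ± 0.272 not called. The camera adjusted p was 7.44e-05, and the adjusted p = 0.589 with an estimated correlation.

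Some markers of blood-derived cells rose beside these groups in CON:CON. Of 6 monocyte markers 4 rose (5 adjusted over the list alone), among them the fibronectin gene Fn1 (6.07 ± 0.976) and Plac8 (count ratio 15.4, 95% interval 3.92 to 132), while Ccr2 (-0.83 ± 0.573) was not called. The other 2 were Chil3 and S100a6, which were not called with both marked libraries included, nor Chil3 without CON_CON_LPS replicate 2 or 5 or CON_CON_SAL replicate 1, 2 or 3, nor S100a6 without any 1 of 7 libraries. Of 6 neutrophil markers 3 rose (5 adjusted over the list alone): the chemokine receptor gene Cxcr2 at least 34.3-fold, the collagenase gene Mmp8 at least 11.5-fold, and S100a8, part of calprotectin, with a count ratio of 73 (12.7 to 2920). Mmp8 and S100a8 were not called without CON_CON_LPS replicate 5 or without any 1 of the 4 CON_CON_SAL libraries. Camera adjusted p values were 0.0886 for monocytes and 0.135 for neutrophils. Scores of homeostatic, interferon, NF-kB, chemokine, MHC class I, complement, monocyte and neutrophil lists each had an exact p of 0.0286 (two-sided), the smallest that 70 relabelings allow, with no overlap between LPS and saline libraries, and 0.0571 after Benjamini-Hochberg. The ribosomal score had an exact p of 0.286.

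The same contrast was made in the other arms. In MIA:CON, the interferon-inducible gene Ifi207 rose by 6.02 ± 0.387, the Fc receptor gene Fcgr4 by 4.81 ± 0.328, the scavenger receptor gene Msr1 by 7.25 ± 0.523, Ifi204 by 4.84 ± 0.364 and Ms4a6d by 3.77 ± 0.295 (log2, SE). The ion transporter gene Slc12a2 changed by -1.86 ± 0.211, Tmem135 by -1.15 ± 0.134, Ttc3 by -1.58 ± 0.188, Gprasp1 by -1.89 ± 0.24 and Srgap2, a regulator of the cytoskeleton, by -1.32 ± 0.17. In CON:PLX, Fcgr4 rose by 5.46 ± 0.332, Ifi207 by 6.14 ± 0.379, Msr1 by 8.00 ± 0.523, Ifi204 by 5.39 ± 0.369 and Ms4a6d by 4.05 ± 0.297, while Lims1 changed by -1.48 ± 0.145, Tmem135 by -1.35 ± 0.133, Srgap2 by -1.70 ± 0.171 and Tet1, a DNA demethylase, by -3.20 ± 0.332. In MIA:PLX, Ifi207 rose by 5.91 ± 0.430, Fcgr4 by 4.90 ± 0.373, Msr1 by 7.58 ± 0.604, Treml2 by 2.90 ± 0.25 and Ifi204 by 4.60 ± 0.403, while Tet1 changed by -3.81 ± 0.376, Srgap2 by -1.77 ± 0.182, Slc12a2 by -2.08 ± 0.226 and P3h2 by -2.16 ± 0.239. The edgeR adjusted p of Ifi207 was 2.2e-13 in MIA:CON and 1.06e-11 in MIA:PLX.

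Genes named in CON:CON were followed in MIA:CON, CON:PLX and MIA:PLX, in that order. P2ry12 fell by 2.19, 3.25 and 3.10 and Tmem119 by 1.23, 1.52 and 1.93. Cd300lf rose by 6.15, 7.58 and 7.31 and Lcn2 by 6.26, 6.13 and 5.95, while Trem1 was at least 122, 308 and 203 times higher. Tnf rose by 2.95, 3.31 and 3.87. Upk1b fell by 3.18, 4.17 and 4.20, Gpr34 by 2.43, 3.73 and 4.32 and Slc2a5 by 2.42, 4.18 and 4.52. Without MIA_CON_LPS replicate 6 the changes in MIA:CON were -3.86 for Gpr34, -3.67 for Slc2a5 and -2.90 for P2ry12. Il1b rose by 3.58 in CON:PLX and was not called in MIA:CON (3.05, edgeR adjusted p 0.0566) or MIA:PLX (3.46, adjusted p 0.0675). In MIA:PLX Ccl2 (1.29) and Cxcl10 (2.06) were not called, and the receptor genes Cx3cr1 (-1.98) and Csf1r (-0.46) fell. Iqcn was not called in these 3 arms (-0.99, -2.78 and -1.84), nor were Itgam, Ptprc and Tlr4. Some of these calls were lost without 1 library: Tmem119 in MIA:CON without MIA_CON_LPS replicate 1, 4 or 5 or MIA_CON_SAL replicate 1, 2 or 4 (-1.03 to -1.23), and Il1b in CON:PLX without CON_PLX_LPS replicate 2 (2.93) or any 1 of the 4 CON_PLX_SAL libraries (3.47 to 3.74). In MIA:PLX, Cx3cr1 was not called without MIA_PLX_SAL replicate 2, 3 or 4 (-1.99, -1.97 and -2.03), nor Csf1r without MIA_PLX_LPS replicate 2 or 4 or MIA_PLX_SAL replicate 2 or 4 (-0.41, -0.42, -0.44 and -0.44).

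By edgeR with Benjamini-Hochberg adjustment, LPS raised 1942 genes and lowered 1462 in MIA:CON (2274 and 1935 without MIA_CON_LPS replicate 6), 2351 and 1872 in CON:PLX, and 1589 and 1402 in MIA:PLX. In all 4 arms 984 genes were higher and 754 lower, and 0 were called in opposite directions in any pair of arms. CON:CON and MIA:CON shared 1307 higher genes (266 expected) and 915 lower (144 expected), and CON:PLX and MIA:PLX shared 1298 (278 expected) and 1118 (196 expected). The correlation of changes across genes, which are not independent replicates, was 0.817 to 0.859 between arms. Voom with quality weights called 6430 genes for LPS in CON:PLX and 4597 for LPS in MIA:PLX, and a fit of only the compared groups called 2226 for LPS in MIA:CON.

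Gene groups in these 3 arms are given in the same order. Homeostatic genes fell in 11, 14 and 16 of 17 members (15, 16 and 16 adjusted over the list alone, and 14 in MIA:CON without MIA_CON_LPS replicate 6), with Siglech at -1.48, -2.15 and -2.03. Interferon-stimulated genes rose in 28, 28 and 25 of 29 (29, 28 and 27 over the list alone), with Zbp1 at 5.41 in CON:PLX and Irf7, a master regulator of interferon responses, at 4.05 in MIA:PLX. NF-kB targets rose in 15, 16 and 14 of 23 (17, 18 and 17 over the list alone), with Bcl3 at 3.53, 4.54 and 3.47, while Marcks fell by 0.98, 1.04 and 1.35. Chemokines rose in 12, 12 and 6 of 14 (12, 12 and 9 over the list alone), with Ccl5 at 7.29, 7.59 and 6.72, while Ccl6 fell by 1.37 in both PLX arms. MIA_PLX_LPS replicate 2 had chemokine and NF-kB scores of 3.15 and 4.45, with the others of its group at 4.97 to 6.15 and 6.31 to 7.44. CON_CON_LPS replicate 4 had 2.91 and 4.42, with the others used at 5.04 to 5.79 and 7.12 to 7.59. Their immediate early and dissociation stress scores were also the lowest of their groups, at 5.28 (others 7.31 to 8.72) and 4.71 (others used 6.99 to 8.50). Saline libraries used had NF-kB scores of 3.71 to 4.91 and interferon scores of 2.11 to 2.91. The interferon scores of these 2 LPS libraries were 5.06 and 5.68. Dissociation stress was not tested as a source of the NF-kB and chemokine changes. MHC class I genes rose in 9, 12 and 7 of 14 (10, 12 and 9 over the list alone), with B2m, the light chain of class I, at 1.13, 1.41 and 1.01. Complement genes rose in 10, 11 and 10 of 18 (10, 11 and 10 over the list alone), with C5ar1 at 2.67, 3.26 and 2.88. In that list the phagocytic receptor gene Mertk (-0.68) and its ligand gene Pros1 (-0.60) fell in MIA:CON, and Gas6 (-2.11) and Pros1 (-0.71) in MIA:PLX. Ribosomal protein genes rose in 34, 35 and 10 of 35 (34, 35 and 19 over the list alone), with Rps2 at 1.47, 1.95 and 1.38. MIA_PLX_LPS replicate 2 had a ribosomal score of 7.04 and the others of its group 7.72 to 8.36, and 19 rose without it. In CON:CON 26 rose without CON_CON_LPS replicate 4, whose score was 6.35, and 4 without CON_CON_LPS replicate 5. Mitochondrial ribosomal RNA stood at 16.9%, 16.8% and 16.1% of counts after LPS in these 3 arms and at 12.6%, 10.7% and 12.5% after saline, and in CON:CON at 12.6% and 11.1%. Marcks, Mertk, Pros1, Gas6 and, outside MIA:PLX, Ccl6 were chosen after their values were seen.

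Camera adjusted p values for these lists in MIA:CON, CON:PLX and MIA:PLX were 3.33e-10, 5.16e-11 and 9.38e-14 for homeostatic genes, with adjusted p = 0.184, 0.149 and 0.137 with an estimated correlation. For interferon-stimulated genes they were 1.81e-16, 1.5e-14 and 1.36e-13, with adjusted p = 0.184, 0.149 and 0.185 with an estimated correlation. NF-kB targets had 0.000125, 5.48e-05 and 0.000562, with adjusted p = 0.355, 0.347 and 0.492 with an estimated correlation. Chemokines had 0.000834, 0.00221 and 0.0222, with adjusted p = 0.298, 0.32 and 0.492 with an estimated correlation. MHC class I genes had 2.15e-06, 8.94e-09 and 1.9e-05, with adjusted p = 0.184, 0.148 and 0.185 with an estimated correlation. Complement genes had 0.000367, 8.58e-05 and 0.00196, with adjusted p = 0.298, 0.23 and 0.492 with an estimated correlation. Ribosomal protein genes had 6.42e-16, 2.09e-16 and 1.27e-06, with adjusted p = 0.298, 0.23 and 0.492 with an estimated correlation. No camera call of any list in any contrast held with an estimated correlation. Exact permutation of list scores (two-sided, Benjamini-Hochberg) gave interferon scores 0.0138, 0.00825 and 0.0387 and homeostatic scores 0.0286, 0.00825 and 0.0387, while the ribosomal score passed in MIA:CON (0.0138) and CON:PLX (0.00825) and not in MIA:PLX (0.146).

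Markers of other cell types moved with LPS in these arms too. Monocyte markers rose in 5, 4 and 5 of 6 members (5, 4 and 5 adjusted over the list alone), with Fn1 at 6.01, 6.33 and 6.72, and Ccr2, the receptor for Ccl2, fell by 1.30 in CON:PLX and 2.40 in MIA:PLX. Neutrophil markers rose in 5, 1 and 2 of 6 (5, 1 and 5 adjusted over the list alone, and 6 in CON:PLX without CON_PLX_SAL replicate 2, whose neutrophil score was 3.43 where the others of its group had -0.74 to -0.06), with Cxcr2 at 4.21 and 2.79 in MIA:CON and CON:PLX and at a count ratio of 70 (95% interval 12.3 to 2790) in MIA:PLX. Camera adjusted p values in MIA:CON and CON:PLX were 0.0426 and 0.0474 for monocytes and 0.0404 and 0.0353 for neutrophils. These were adjusted p = 0.239 and 0.219 for monocytes and adjusted p = 0.438 and 0.41 for neutrophils with an estimated correlation. The neutrophil call was lost in MIA:CON without MIA_CON_LPS replicate 2, 3 or 6 or MIA_CON_SAL replicate 3 or 4 (0.0505 to 0.0842), and in CON:PLX without CON_PLX_SAL replicate 1 or 3 (0.0662 and 0.0621). Neutrophil scores (log2 CPM, SD) were 1.41 ± 1.52, 1.97 ± 1.43, 2.51 ± 0.207 and 2.46 ± 1.37 after LPS in CON:CON, MIA:CON, CON:PLX and MIA:PLX, and -0.57 ± 0.244, -0.35 ± 0.569, 0.47 ± 2.00 and 0.00 ± 0.553 after saline. Homeostatic scores after LPS were 8.06 ± 0.698, 8.48 ± 0.796, 8.08 ± 0.646 and 8.09 ± 0.179, and between 10.01 and 10.15 after saline.

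**Figure D2:**
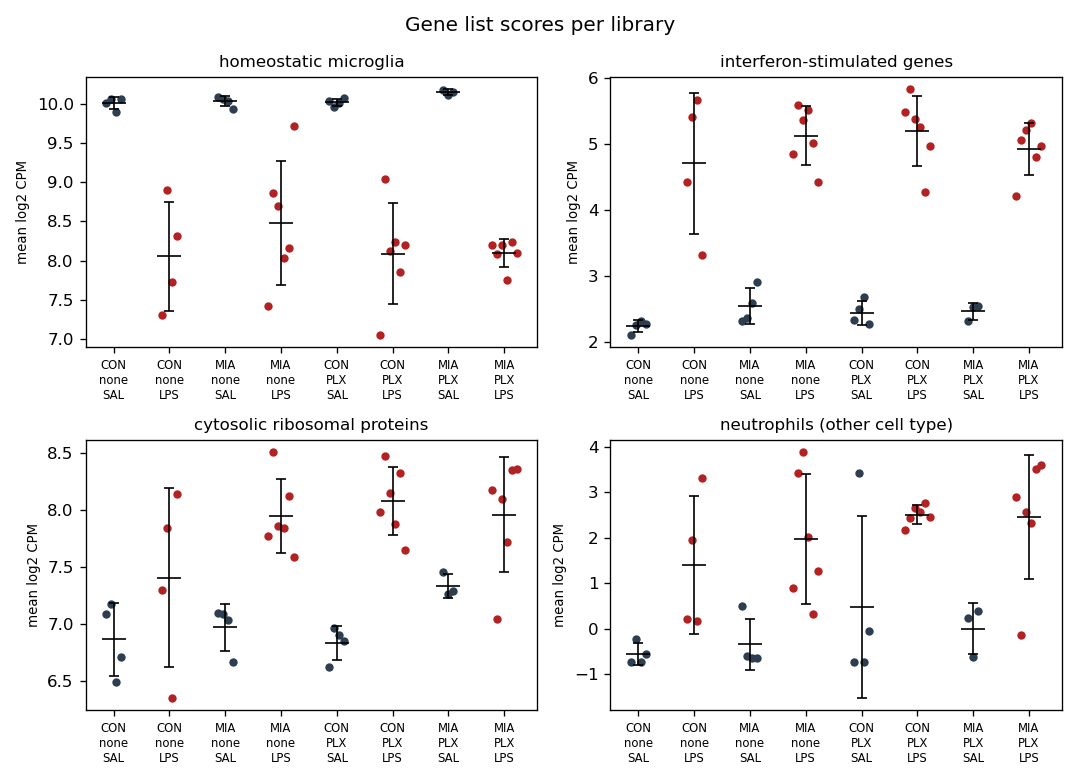
Mean log2 CPM per library (vertical axis) of the homeostatic, interferon-stimulated, ribosomal protein and neutrophil lists in the 8 groups, with bars for group mean ± SD. Interferon scores lie at 4.71 to 5.20 on average after LPS and at 2.24 to 2.55 after saline, and 1 CON_PLX_SAL library has a neutrophil score of 3.43.

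The other lists gave these counts for LPS in CON:CON, MIA:CON, CON:PLX and MIA:PLX, in that order, with counts adjusted over the list alone in parentheses. LPS sensing genes rose in 6, 5, 7 and 3 of 17 members (6, 6, 7 and 4) and fell in 2, 1, 2 and 2 (4, 2, 2 and 3). Disease-associated microglia genes rose in 6, 5, 8 and 7 of 17 (7, 6, 10 and 7) and fell in 3, 3, 4 and 5 (3, 3, 4 and 5). Oxidative phosphorylation genes rose in 3, 12, 17 and 4 of 21 (1, 14, 18 and 0), glycolysis genes in 7, 7, 10 and 6 of 16 (7, 7, 11 and 8), with 1 fall in CON:CON, and cholesterol synthesis genes in 7, 5, 4 and 6 of 19 (8, 5, 3 and 6). MHC class II genes rose in 1, 1, 2 and 1 of 6 (1, 1, 2 and 1) and brain-engrafted macrophage genes in 2 of 5 in each arm (2 in each), with 1 fall in MIA:PLX. Cell cycle genes rose in 2, 2, 3 and 2 of 13 (2, 2, 4 and 2), with 1 fall in each PLX arm, immediate early genes in 4, 4, 5 and 4 of 18 (4, 4, 5 and 4) and unfolded protein response genes in 2, 2, 2 and 1 of 12 (0, 2, 2 and 1). Camera called immediate early and dissociation stress genes higher in MIA:CON (adjusted p 0.0234, and adjusted p = 0.559 with an estimated correlation). Brain-engrafted macrophage genes were called higher there too (0.0478, and adjusted p = 0.353 with an estimated correlation). In MIA:PLX the median and the camera direction of the unfolded protein response differed in sign (-0.0239, up), as did the medians of MHC class II in CON:CON (-0.218, up) and MIA:PLX (-0.148, up) and of brain-engrafted macrophage genes in MIA:PLX (-0.222, up), whose means were above 0.

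Markers of other brain cells were seldom called after LPS. Neuron markers rose in 0, 0, 1 and 0 of 7 members (0 in each adjusted over the list alone), oligodendrocyte markers in 0 of 5 in each arm (0 in each) and border-associated macrophage markers in 1, 0, 1 and 0 of 6 (1, 0, 1 and 0). Of 7 astrocyte markers 1 rose and 1 fell in MIA:CON (1 and 1) and 0 were called in the other arms (0). Endothelial and mural markers fell in 1, 0, 2 and 1 of 4 (1, 0, 2 and 2) and erythroid markers in 0, 0, 2 and 0 of 2 (0, 0, 2 and 0). The 1 measured lymphocyte marker was not called over all genes and fell in each arm when adjusted over the list alone. In MIA:PLX the camera direction of astrocyte markers (up) and border-associated macrophage markers (down), and in CON:PLX that of oligodendrocyte markers (down), differed in sign from the mean (-0.0137, 0.194 and 0.119).

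The central question of the design is whether the LPS response differs after prenatal MIA, and whether the PLX arm changes that. Without PLX, the response over 2580 genes was 1.45 ± 0.165 log2 units (SE) in MIA and 1.56 ± 0.107 in CON, a difference of -0.11 ± 0.196 with an exact permutation p of 0.687 (two-sided, 14700 splits). With PLX, over 2166 genes, it was 1.69 ± 0.0766 in MIA and 1.71 ± 0.126 in CON, a difference of -0.02 ± 0.147 with an exact permutation p of 0.897 (32340 splits). Both differences were smaller than their SE, and both changed sign when 1 library was left out. Without MIA_CON_LPS replicate 6, the first was 0.04. The second was 0.08 without CON_PLX_LPS replicate 1, 0.02 without CON_PLX_LPS replicate 5 and 0.04 without MIA_PLX_LPS replicate 2. With both marked libraries included the first was 0.15.

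**Figure D3:**
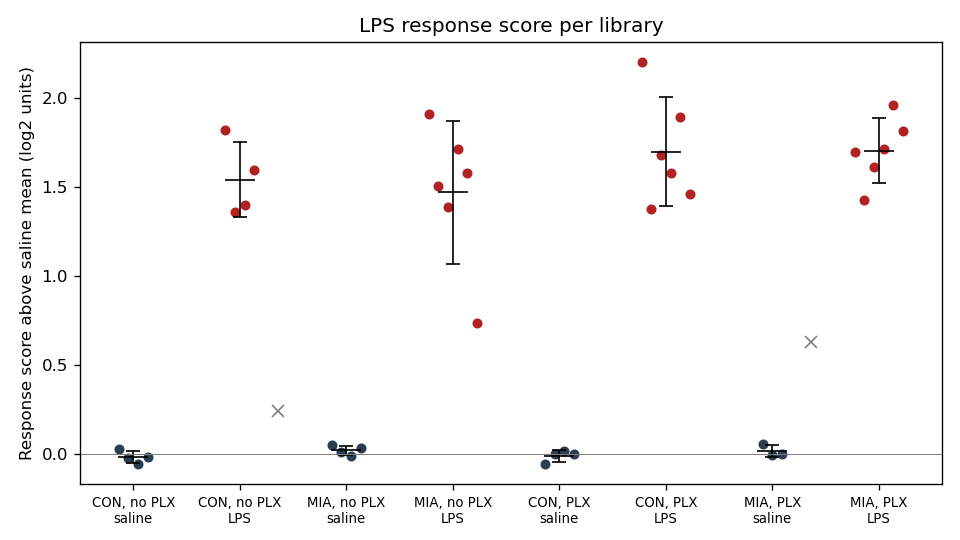
Response score of each library above the mean of the saline libraries, MIA and CON together, with or without PLX as the library itself (vertical axis, mean log2 units) in the 8 groups, with bars for mean ± SD and crosses for the 2 libraries whose titles say exclude. LPS libraries lie between 0.737 and 2.2 and saline libraries between -0.059 and 0.054, apart from the crosses at 0.243 and 0.629.

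MIA was compared with CON without PLX. After LPS, P2ry12 was at 605 ± 580 CPM in MIA (SD, n = 6) and 279 ± 87.6 in CON (SD, n = 4), a log2 difference of 1.12 ± 0.334 (SE) that did not pass (edgeR adjusted p 0.386) and was 0.41 ± 0.2 without MIA_CON_LPS replicate 6. B2m (0.56 ± 0.17), the immunoproteasome gene Psmb10 (0.71), Siglech (0.60 ± 0.241) and the ribosomal protein genes Rpl26 (0.79 ± 0.263) and Rpl27 (0.68) did not pass either. EdgeR called 0 genes after LPS (1253 at an unadjusted p under 0.05, 7 by DESeq2, 0 by voom) and 0 after saline (160, 0 and 1), where P2ry12 differed by 0.23 ± 0.352. Chance would give 671 genes at that level, and other splits of these saline libraries gave a median of 132. The fit of all groups was thus conservative for saline libraries, so 0 calls there do not show an absence of difference. After LPS 1 homeostatic gene of 17, P2ry12, passed when adjusted over the list alone, as did 1 of 14 MHC class I genes and 1 of 7 astrocyte markers, and 0 of each over all genes. After saline, Cxcl9 passed over the list of chemokines alone, at 2.95 ± 4.48 CPM in MIA and 0 in CON (SD, n = 4 each), and not over all genes. Camera called ribosomal protein genes higher in MIA after LPS (adjusted p 2.45e-17, and adjusted p = 0.254 with an estimated correlation), and likewise homeostatic genes (6.7e-05, and adjusted p = 0.331 with an estimated correlation) and MHC class I (0.00035, and adjusted p = 0.254 with an estimated correlation). The ribosomal difference came with mitochondrial ribosomal RNA at 16.9% of counts in MIA_CON_LPS against 12.6% in CON_CON_LPS, where replicate 4 had a ribosomal score of 6.35 and the others 7.30 to 8.13. Without that library the score difference went from 0.54 to 0.19 (camera adjusted p 0.00268, and adjusted p = 0.728 with an estimated correlation). MIA_CON_LPS replicate 6 had a homeostatic score of 9.72 and the others of its group 7.41 to 8.86, and the difference from CON went from 0.42 to 0.18 without it (camera adjusted p 0.0212, and adjusted p = 0.514 with an estimated correlation) and to 0.17 without CON_CON_LPS replicate 1 (0.0406, and adjusted p = 0.85 with an estimated correlation). It went to 0.70 without CON_CON_LPS replicate 2 (4.68e-08, and adjusted p = 0.167 with an estimated correlation) and to 0.64 without MIA_CON_LPS replicate 1 (1.49e-07, and adjusted p = 0.241 with an estimated correlation). Astrocyte markers were also higher by camera (0.000172, and adjusted p = 0.0673 with an estimated correlation), with a score 1.07 higher in MIA (exact permutation p 0.019, two-sided, 0.248 after Benjamini-Hochberg). Other lists were called higher too, among them endothelial and mural cells (0.00853), neurons (0.0141), oligodendrocyte lineage (0.0145), oxidative phosphorylation (6.97e-07) and immediate early genes (0.00348). In the same order the adjusted p = 0.0673, 0.331, 0.223, 0.254 and 0.579 with an estimated correlation. Leaving out MIA_CON_LPS replicate 1 or replicate 6 gave 1 called gene after LPS.

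MIA was next compared with CON in saline libraries with PLX, where genes for the protein part of the ribosome stood higher in MIA without passing in the fit of all groups. Rps18 differed by 0.79 ± 0.328 (log2, SE), Rps19 by 0.78, Rpl19 by 0.63 and Rpl24 by 0.62, B2m by 0.52 ± 0.197 and H2-D1 by 0.55 ± 0.260. In the fit of all 8 groups edgeR called 0 genes (163 at an unadjusted p under 0.05 where chance would give 671, 0 by DESeq2, 1 by voom), with an adjusted p of 1 for B2m and Rps18. A fit of only these 7 libraries called 124 genes higher and 12 lower of 11962 tested, among them 26 of 35 ribosomal protein genes, 3 of 14 MHC class I genes and 3 of 18 complement genes, all higher. In that fit B2m differed by 0.52 ± 0.0635 (edgeR adjusted p 0.000172) and Rps18 by 0.80 ± 0.101. Abundant transcripts outside those lists were among the 124 too and moved about as far as B2m. Chosen after their values were seen, they included Cst3 (0.52), Ftl1 (0.58), Gapdh (0.46), Tmsb4x (0.50) and Ppia (0.50). Mitochondrial RNA was higher in MIA too, with mt-Rnr1 (0.35 ± 0.0622), mt-Rnr2 (0.28), mt-Co2 (0.80), mt-Nd1 (0.38) and mt-Nd3 (0.63), chosen after their values were seen, among the 124, and mitochondrial ribosomal RNA at 12.5% of counts in MIA_PLX_SAL and 10.7% in CON_PLX_SAL. The count was 80 without CON_PLX_SAL replicate 1, 90 without CON_PLX_SAL replicate 4, 87 without MIA_PLX_SAL replicate 2 and 208 without MIA_PLX_SAL replicate 3. Camera gave ribosomal protein genes an adjusted p of 1.13e-23 and MHC class I one of 2.03e-05, each with adjusted p = 0.462 with an estimated correlation. Among others, it also called immediate early and dissociation stress genes (2.87e-05) and oxidative phosphorylation (0.000103) higher, each with adjusted p = 0.593 with an estimated correlation. Astrocyte markers were called lower in MIA (0.0282, and adjusted p = 0.463 with an estimated correlation). The ribosomal score was 7.33 ± 0.104 in MIA (SD, n = 3) and 6.83 ± 0.149 in CON (SD, n = 4), without overlap (exact permutation p 0.0286, two-sided, the smallest that 35 splits allow, and 0.0929 after Benjamini-Hochberg). Without PLX the saline ribosomal scores were 6.97 ± 0.206 in MIA and 6.86 ± 0.319 in CON (SD, n = 4 each).

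After LPS with PLX, 2 genes were higher in MIA: Sbsn, which encodes suprabasin of cornified epithelium, by 3.19 ± 0.556 and Ppl, a plakin that links cell junctions to filaments, by 2.25 ± 0.407 (log2, SE, edgeR adjusted p 0.0194 for each). Both lie below the level of the naming rule, at average log2 CPM of 2.44 and 1.71, and were chosen after their values were seen. The chemokine gene Ccl12 (-2.14 ± 0.814) and Fdft1 of sterol synthesis (1.04 ± 0.258) did not pass over all genes, and Fdft1 was the 1 cholesterol gene that passed over the list alone. EdgeR found 1193 genes at an unadjusted p under 0.05, DESeq2 called 14 and voom 1, while a fit of only these 2 groups called 0. The count was 0 without CON_PLX_LPS replicate 2, 3 or 5, 5 without MIA_PLX_LPS replicate 2 and 4 without MIA_PLX_LPS replicate 6.

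PLX was compared with none. In CON after LPS, Nbea (ENSMUSG00000027799.12), which encodes a scaffold of membrane traffic, was lower with PLX, at 35.3 ± 6.59 CPM (SD, n = 6) against 64.6 ± 5.78 (SD, n = 4), a log2 change of -0.87 ± 0.147 with an edgeR adjusted p of 0.012. Its saline levels in CON were 70.7 ± 13.4 and 119 ± 11.9 CPM (SD, n = 4 each), which did not pass (-0.75 ± 0.161, edgeR adjusted p 0.54), and in MIA after LPS they were 39.9 ± 5.73 and 52.6 ± 3.99 (SD, n = 6 each; -0.40 ± 0.137, edgeR adjusted p 0.377). Nbea was the 1 gene called (943 at an unadjusted p under 0.05, 1 by DESeq2, 0 by voom) and was not called without CON_CON_LPS replicate 1 or 4 or CON_PLX_LPS replicate 2, 3 or 5 (-0.81, -0.88, -0.81, -0.81 and -0.83). B2m (0.63 ± 0.17) and Psmb10 (1.07 ± 0.277) had edgeR adjusted p values of 0.573, and 4 of 14 MHC class I genes (B2m, Psmb10, Psme2 and Tapbp) passed when adjusted over the list alone and 0 over all genes. Camera called MHC class I higher with PLX (4.25e-09, and adjusted p = 0.127 with an estimated correlation) and ribosomal protein genes higher (5.54e-26, and adjusted p = 0.17 with an estimated correlation), as well as neutrophil markers (0.00606, and adjusted p = 0.296 with an estimated correlation). All lists that camera called here were higher, most of the lists tested. They included oxidative phosphorylation (1.26e-11), interferon-stimulated genes (3.82e-05), astrocytes (0.00123), oligodendrocyte lineage (0.0203) and neurons (0.0233). In the same order the adjusted p = 0.17, 0.3, 0.17, 0.17 and 0.3 with an estimated correlation. The shift was thus not particular to MHC class I and ribosomal proteins. The neutrophil call was lost without CON_CON_LPS replicate 1 (0.0802) or 4 (0.0682), and the ribosomal score difference went from 0.67 to 0.32 without CON_CON_LPS replicate 4. Mitochondrial ribosomal RNA took 16.8% of counts in CON_PLX_LPS and 12.6% in CON_CON_LPS.

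In MIA after LPS, P2ry12 was -0.92 ± 0.291 (log2, SE) with PLX against none, Olfml3, a secreted glycoprotein of microglia, -1.34 ± 0.447 and Slc2a5 -1.88 ± 0.680, none of which passed over all genes (edgeR adjusted p 0.338 for P2ry12). Adjusted over the list alone, 2 of 17 homeostatic genes passed (P2ry12 and Olfml3), and camera called the list lower with PLX (0.00127, and adjusted p = 0.845 with an estimated correlation). Without MIA_CON_LPS replicate 6, whose homeostatic score was 9.72, the list was not called (camera adjusted p 0.251), the score difference went from -0.39 to -0.14, and P2ry12 was -0.21, Olfml3 -0.92 and Slc2a5 -0.63. Without MIA_CON_LPS replicate 1 the score difference was -0.60 (camera adjusted p 1.43e-07, and adjusted p = 0.309 with an estimated correlation). Astrocyte markers were also called lower with PLX in all libraries used (camera adjusted p 0.017, and adjusted p = 0.397 with an estimated correlation). EdgeR called 0 genes (1192 at an unadjusted p under 0.05, 25 by DESeq2, 0 by voom). It called 16 without MIA_PLX_LPS replicate 2, 4 without MIA_PLX_LPS replicate 4 or MIA_CON_LPS replicate 6, 2 without MIA_PLX_LPS replicate 5 or MIA_CON_LPS replicate 1, and 1 without MIA_CON_LPS replicate 2, 3 or 4. After saline, edgeR called 0 genes in CON (124 at an unadjusted p under 0.05, 1 by DESeq2, 1 by voom) and 0 in MIA (159, 1 and 1). Both counts at that level lie below the 671 that chance would give, so these 0 calls do not show an absence of difference. Neutrophil markers passed in 5 of 6 in CON saline when adjusted over the list alone, where S100a9 stood at 37.2 CPM in CON_PLX_SAL replicate 2 and at most 3.15 in the other 14 saline libraries. Camera called ribosomal protein genes higher with PLX in MIA saline libraries (7.44e-14, and adjusted p = 0.896 with an estimated correlation), where Rpl30 differed by 0.56 ± 0.293. Camera also called disease-associated microglia genes there (0.0316, up, and adjusted p = 0.896 with an estimated correlation), with a median of 0.137 and a mean of -0.0348.

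The interactions asked directly whether LPS effects differ between arms. P2ry12 differed by 0.89 ± 0.480 (log2, SE) between LPS effects in MIA and CON without PLX, with an edgeR adjusted p of 1, and by 0.18 ± 0.289 without MIA_CON_LPS replicate 6. EdgeR called 0 genes for MIA by LPS without PLX, MIA by LPS with PLX, PLX by LPS in CON, PLX by LPS in MIA and the interaction of all 3 factors. At an unadjusted p under 0.05 there were 416, 393, 354, 389 and 440 genes, where 671 would be given by chance. DESeq2 and voom called 0 in each. For no single gene was the LPS effect shown to differ between arms. Counts below chance point to a conservative test, so they do not show that the effects were equal. No list score passed exact permutation after Benjamini-Hochberg in a comparison of MIA with CON, of PLX with none, or for MIA by LPS. For MIA against CON in saline with PLX only 35 splits exist, with a smallest exact p of 0.0286 by permutation. In comparisons between groups a single list could not pass after adjustment over 26 lists, whatever its difference. The outcomes of those comparisons are therefore no evidence that the scores were equal. For MIA by LPS, with 14700 splits without PLX and 32340 with PLX, a single list could have passed. That none did there does not show equal scores either.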

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

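The tests on ribosomal protein genes, on MIA_CON_LPS replicate 6, on Lcn2 and on the spread of LPS libraries were chosen only after the results were seen. The counts of other splits were planned, and the one for the fit of 7 saline libraries was added once its 136 genes were known, before its splits were run.

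Libraries far from the rest of their group were sought in 49 combinations of a group and a measure (7 measures in the groups of 4 or more), and 6 were found. For normal values chance gives about 1 in 20, as 5.09% and 5.11% of simulated normal groups of 4 and 6 met the rule. Neutrophil and erythroid scores of many saline libraries lie at or near -0.74, their floor at 0 counts. That rate need not hold for such scores, and theirs was not simulated. The homeostatic score of MIA_PLX_LPS replicate 4 was 7.75 log2 CPM, with the others at 8.08 to 8.23. The ribosomal score of MIA_CON_SAL replicate 4 was 6.66, with the others at 7.03 to 7.09. The neutrophil score was 3.43 in CON_PLX_SAL replicate 2 (others -0.74 to -0.06), 0.51 in MIA_CON_SAL replicate 1 (others -0.64 to -0.61) and -0.13 in MIA_PLX_LPS replicate 2 (others 2.32 to 3.60). The erythroid score of CON_CON_SAL replicate 2 was 3.09, with the others at -0.74 to -0.49. CON_PLX_SAL replicate 2 held the neutrophil transcripts S100a9 at 37.2 CPM, Ngp at 28.8 and Ltf at 12.3, against at most 3.15, 1.95 and 1.26 in the other 14 saline libraries, and the hemoglobin transcript Hbb-bs at 70 against at most 15.1.

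Of the libraries whose titles say exclude, CON_CON_LPS replicate 3 had a response score of 0.243, below the 4 other libraries of its group at 1.36 to 1.82. MIA_PLX_SAL replicate 1 had 0.629, above the highest score of 0.054 in its group.

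Several gene lists differed in their LPS effect between arms by camera with its preset correlation, and none did with an estimated one. These tests were not run again without single libraries, MIA_CON_LPS replicate 6 among them. That library had a homeostatic score of 9.72, and the others of its group 7.41 to 8.86. Without it, the homeostatic call for PLX against none in MIA after LPS was lost. For MIA by LPS without PLX the adjusted p was 0.00179 for homeostatic genes, 0.033 for oxidative phosphorylation, 8.74e-09 for ribosomal proteins, 0.0481 for astrocytes and 0.0485 for endothelial and mural cells. In the same order the adjusted p = 0.768, 0.941, 0.768, 0.751 and 0.341 with an estimated correlation. For MIA by LPS with PLX it was 0.000211 for MHC class I, 0.00128 for glycolysis, 0.000167 for oxidative phosphorylation, 4.25e-16 for ribosomal proteins and 0.00263 for the unfolded protein response, each with adjusted p = 0.562 with an estimated correlation.

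For PLX by LPS in CON it was 7.84e-07 for MHC class I, 0.0418 for MHC class II, 0.0418 for complement, 0.000113 for glycolysis, 3.26e-06 for oxidative phosphorylation, 1.14e-20 for ribosomal proteins and 0.00111 for neurons. In the same order the adjusted p = 0.329, 0.414, 0.746, 0.402, 0.414, 0.402 and 0.402 with an estimated correlation. For PLX by LPS in MIA it was 0.000281 for homeostatic genes and 2.81e-06 for ribosomal proteins, both with adjusted p = 0.961 with an estimated correlation. For the interaction of all 3 factors it was 0.0212 for homeostatic genes, 0.00065 for MHC class I, 0.00419 for glycolysis, 7.58e-06 for oxidative phosphorylation, 5.71e-23 for ribosomal proteins, 0.0151 for the unfolded protein response, 0.0384 for neurons and 0.0384 for the oligodendrocyte lineage. In the same order the adjusted p = 0.593, 0.448, 0.477, 0.448, 0.448, 0.508, 0.477 and 0.448 with an estimated correlation.

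Ribosomal protein transcripts were higher in MIA than in CON saline libraries with PLX, with a median log2 difference of 0.513 over 35 genes, and mitochondrial ribosomal RNA moved with them (12.5% of counts in MIA_PLX_SAL and 10.7% in CON_PLX_SAL). Immediate early and dissociation stress genes were higher too (camera adjusted p 2.87e-05, and adjusted p = 0.593 with an estimated correlation). Dissociation stress was not tested as a source of the ribosomal shift. Better recovery of short transcripts is argued against by 958 other genes of like length and abundance, with a median of -0.0184 (interval -0.0252 to -0.00438), and by a closer match of 2685 genes, tried second, with 0.00586 (-0.0117 to 0.0241) and ribosomal genes 0.455 above their matches (exact permutation p 0.0286, two-sided, the smallest that 35 splits allow). Both intervals come from resampling genes, so they hold no spread between libraries. Coding genes under 1100 nucleotides had medians of 0.0244, 0.0238, 0.0722, 0.151 and 0.199 at a minimum log2 CPM of 6, 7, 8, 9 and 10 (330, 161, 69, 30 and 14 genes). A bias on short and very abundant transcripts may therefore remain. LPS-treated material in the MIA libraries is argued against, since the shift would need a response score of 0.757 and the highest was 0.054. Depth stays open (15 saline libraries, group-centred r 0.125 with permutation p 0.675, rho 0.268 with permutation p 0.395, r 0.0707 without the 2 farthest, interval -0.484 to 0.652), as do a change in RNA composition that mitochondrial RNA shares and prenatal MIA itself, neither of which was tested apart from these.

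MIA_CON_LPS replicate 6 had the weakest response of the LPS libraries used, at a score of 0.737. Material shared with MIA_PLX_SAL replicate 1, whose title says exclude, may account for it: the 2 libraries differed by a chi-square per degree of freedom of 1.66, the lowest of 741 pairs and below the 2.85 of the closest pair within a group, and by 1.23 over 1895 genes with little LPS change (2.58 for the next pair). A wrong label stays open by its test, since the highest score of the 15 saline libraries used was 0.054 but the marked saline library had 0.629. That marked library is the one that replicate 6 nearly matched, so it gives no independent saline level. Against the 15 others, 0.737 stood far above the range. A mixture of LPS and saline material cannot be told apart from a weaker response by its own test: the library showed 0.387 of the rise and 0.42 of the fall of the other libraries, a difference of -0.0323 where 2 SD of the others is 0.304. A weaker response of this sample's microglia was not tested apart from this.

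Lcn2, a member of the NF-kB list and not of the neutrophil list, rose with LPS in every arm, as did some neutrophil markers. RNA from neutrophils as the source of Lcn2 is argued against, because those cells carry more S100a8 and S100a9 than Lcn2, and Lcn2 lay above both in 22 of 22 LPS libraries (exact 95% interval 84.6% to 100%), with medians of 116, 10.9 and 12.8 CPM for Lcn2, S100a8 and S100a9. The gate for CD45-low P2RY12-positive cells does not exclude neutrophil RNA, since S100a9 reached 37.2 CPM in CON_PLX_SAL replicate 2. Cell types other than neutrophils were not tested as a source. Expression by microglia after LPS is a candidate explanation and a hypothesis, found and tested on the same data.

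A residual component (21.97% of the residual variance) along which 22 LPS libraries spread was tested and is not weighed. Its group-centred r over 3 relations was 0.289 with depth (permutation p 0.232, Benjamini-Hochberg 0.348; rho 0.324, p 0.173; r without the 2 farthest 0.253), 0.379 with the dissociation stress score (permutation p 0.0847, Benjamini-Hochberg 0.254; rho 0.544, p 0.00956; 0.614) and 0.0352 with the ribosomal RNA share (permutation p 0.891, Benjamini-Hochberg 0.891; rho 0.126; interval -0.426 to 0.482).

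Other splits of the same libraries were counted. For LPS, 1 of 35 splits in CON:CON (real 3160 genes, highest other 360), 1 of 100 in MIA:CON (3404, 2258), 1 of 100 in CON:PLX (4223, 1888) and 1 of 84 in MIA:PLX (2991, 395) called as many genes, the real split included. For MIA against CON with PLX after LPS 7 of 100 did (2, 84), and for PLX against none in CON after LPS 22 of 100 (1, 279). At an unadjusted p under 0.05, for MIA against CON, 9 of 35 splits gave as many after saline without PLX (160, 236), 51 of 100 after LPS without PLX (1253, 5435) and 1 of 35 after saline with PLX (163, 127). For PLX against none the counts were 4 of 35 in CON saline (124, 149), 9 of 35 in MIA saline (159, 215) and 42 of 100 in MIA after LPS (1192, 4087). For the interactions they were 66 (416, 3315), 15 (393, 673), 55 (354, 1375), 51 (389, 1571) and 33 of 100 (440, 2140), in the order MIA by LPS without and with PLX, PLX by LPS in CON and in MIA, and all 3 factors. In the fit of 7 saline libraries with PLX, 1 of 35 splits called as many (136, 13). Splits of LPS libraries that gave several times the real count point to a structure of those libraries other than the groups.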

How the results depend on the processing

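The residual covariate and the joint removal of MIA_CON_LPS replicate 6 and CON_PLX_SAL replicate 2 were chosen after seeing the data. Of counts and response sizes, 147 values under other settings and 235 without 1 library stayed within 1.5 times or kept their direction. Another 32 and 20 moved further, and 1 and 4 reversed. Without 1 library, every interaction and every saline comparison of MIA or PLX gave 0 genes, as in the main fit. These count among the 235 and do not show robustness, since that fit was conservative there. Of values of named genes 669 and 1519 kept direction and side of the threshold, 14 and 65 lost the call, 16 and 12 gained it, and 4 and 19 reversed. List calls held in 102 cases and were lost in 69, of which 57 were with an estimated correlation, 7 with both marked libraries included and 5 with the block. The causes below were not tested, except that fewer libraries or genes enter some fits.

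DESeq2 called 7 genes for MIA after LPS without PLX, 14 after LPS with PLX, and for PLX 1 in CON saline, 1 in MIA saline and 25 in MIA after LPS. Voom called 6430 for LPS in CON:PLX, 4597 for LPS in MIA:PLX, 1 for MIA in saline without PLX, 1 in saline with PLX, 1 after LPS with PLX, and for PLX 1 in CON saline, 1 in MIA saline and 0 in CON after LPS. Without a filter, MIA after LPS with PLX gave 5, PLX after LPS 0 in CON and 3 in MIA. The stricter filter gave 1 for MIA after LPS with PLX. A replicate block gave 0 there, and for PLX after LPS 2 in CON and 4 in MIA. The residual covariate gave 7 for MIA after LPS without PLX, and for PLX after LPS 3 in CON and 56 in MIA. That covariate was the largest component of the spread within groups in these same libraries. It takes spread out of the tested values by construction, so more calls with it are no support for a difference. The joint removal gave 1 for MIA after LPS without PLX and 2 for PLX in MIA after LPS.

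Fitting only the compared groups gave 2226 for LPS in MIA:CON, for MIA 1 after LPS without PLX, 136 in saline with PLX and 0 after LPS with PLX, and for PLX 10 in CON saline, 0 in CON after LPS and 2 in MIA saline.

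Leaving out 1 library gave 2453 to 3183 genes for LPS in CON:CON, 2587 to 4209 in MIA:CON, 3452 to 4388 in CON:PLX and 2002 to 3134 in MIA:PLX. It gave 0 to 1 for MIA after LPS without PLX (1 without MIA_CON_LPS replicate 1 or 6), 0 to 5 with PLX (0 without CON_PLX_LPS replicate 2, 3 or 5, and 5 without MIA_PLX_LPS replicate 2), 0 to 1 for PLX in CON after LPS and 0 to 16 in MIA after LPS (16 without MIA_PLX_LPS replicate 2).

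The response size difference without PLX reversed to 0.146 with both marked libraries included and ran from -0.196 to 0.0381 without 1 library (above 0 without MIA_CON_LPS replicate 6). With PLX it ran from -0.0842 to 0.0803.

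Genes that reversed were not called. With both marked libraries C1qc became 0.21 in CON:CON and the Itgam log2 fold change, LPS in CON:CON, became 0.0395. With the block Tlr4 became 0.0193 in CON:CON and 0.0631 in MIA:PLX. Without 1 library in CON:CON, C1qc ran from -0.22 to 0.14, Tap2 from -0.35 to 0.0894, Itgam from -0.40 to 0.12, Tlr4 from -0.31 to 0.19 and Ifit3b from -0.10 to 0.97. The Nfkb1 log2 fold change, LPS in CON:CON, ran from -0.00587 to 0.33, and the Rpl30 log2 fold change, LPS in CON:CON, from -0.00714 to 0.50. In MIA:PLX, Itgam ran from -0.27 to 0.0062, the Ptprc log2 fold change, LPS in MIA:PLX, from -0.0925 to 0.17 and Tlr4 from -0.20 to 0.0428.

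Replicate numbers were not taken to pair libraries, since the labels do not say so and residual correlations of libraries with the same number ran from -0.245 to 0.663 (median 0.0179, and -0.00452 for different numbers). As a hint from the data and not the design, 15 of 37 libraries, not all, correlated best with one of their own number. Of the pairs compared, 107 had the same number and 487 different numbers, so chance alone would give fewer. On the residual component LPS replicate 1 stood at -64.2, -61.1 and -72.6 and replicate 2 at 35.2, 32.6 and 54.1 in CON_CON, CON_PLX and MIA_CON, but at 18.8 and 4.79 in MIA_PLX, so some numbers may share a structure. With the block Chil3, S100a6, S100a8 and Mmp8 in CON:CON and Il1b in CON:PLX were not called.

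Other named genes lost a call as follows. With both marked libraries included they were Slc2a5, Gpr34, Gpr165, Chil3, S100a6, Mmp8 and Tmem119 in CON:CON and Marco and Csf1r in MIA:PLX. Without 1 library they were Ccl2, Chil3, S100a6, S100a8, Mmp8 and Rpl14 (0.72 without CON_CON_LPS replicate 5) in CON:CON, Il1b and Ccl2 in CON:PLX, Tmem119, Acod1 and Ccl2 in MIA:CON, Marco, Cx3cr1 and Csf1r in MIA:PLX, and Nbea. Ccl2 was 1.94 to 2.34 in CON:PLX without CON_PLX_LPS replicate 2 or CON_PLX_SAL replicate 2 or 4, and 1.64 to 2.50 in MIA:CON without MIA_CON_LPS replicate 3 or MIA_CON_SAL replicate 2, 3 or 4.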

Other observations

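Genes of energy and sterol metabolism also changed after LPS, given here for CON:CON, MIA:CON, CON:PLX and MIA:PLX, in that order. Oxidative phosphorylation genes, which build the mitochondrial respiratory chain, rose in 3, 12, 17 and 4 of 21. The camera adjusted p was 0.00757, 3.49e-06, 1.38e-07 and 0.00163, and adjusted p = 0.573, 0.298, 0.23 and 0.492 with an estimated correlation. Cholesterol synthesis genes rose in 7, 5, 4 and 6 of 19, with a camera adjusted p of 0.0042, 0.029, 0.0119 and 0.00296, and adjusted p = 0.115, 0.184, 0.149 and 0.11 with an estimated correlation. Glycolysis genes rose in 7, 7, 10 and 6 of 16, with a camera adjusted p of 0.0408, 0.00317, 8.58e-05 and 0.0202, and adjusted p = 0.573, 0.353, 0.23 and 0.492 with an estimated correlation. Differences between arms in these counts were not tested as such. For single genes edgeR called 0 in any interaction. Camera with its preset correlation called oxidative phosphorylation for MIA by LPS without PLX (adjusted p 0.033) and with PLX (0.000167), for PLX by LPS in CON (3.26e-06) and for all 3 factors (7.58e-06), with adjusted p = 0.941, 0.562, 0.414 and 0.448 with an estimated correlation. It called glycolysis for MIA by LPS with PLX (0.00128), PLX by LPS in CON (0.000113) and all 3 factors (0.00419), with adjusted p = 0.562, 0.402 and 0.477 with an estimated correlation.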
